A study of fermentation metagenome and mouse metagenome with 26 samples.

How the data were processed

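Fermenting grain of highland barley liquor, a Chinese spirit, and mouse cecal contents were profiled by amplicon sequencing. Per the series description, the fermentation was preceded by a pretreatment with the bacterium Lactobacillus delbrueckii, fungi were read from the ITS and bacteria from the V3-V4 region of the 16S rRNA gene, and mice received the distilled products by gavage for 3 days. The series lists 26 samples, of which 11 are bacterial and 11 fungal samples of grain and 4 are cecal samples. The fungal grain samples are control grain on days 0, 4, 13 and 26, pretreated grain on days 0, 4, 13 and 26 of formal fermentation, and grain in pretreatment on days 0, 3 and 7. The cecal samples are from mice given distilled water, edible alcohol, control liquor or pretreated liquor.

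The deposited tables hold counts, that is whole numbers of reads per genus and library, and the authors had assigned the reads to genera before deposit. Per the labels' protocols, DNA was extracted with a magnetic soil and stool kit, the 16S region was amplified with primers 338F and 806R, and fragments were read as 2 x 250 bases on an Illumina Novaseq 6000. The same protocol text stands with every sample, so the ITS primers are not given in the sources used here, nor are the clustering, the classifier, its database and the quality filters. Each sample of the labels has 3 numbered libraries in the tables. Whether these are separate fermentations, animals or repeats of the same DNA is not given in the sources used here, and p-values measure only the spread between libraries, which may be technical. The table of grain bacteria held the same values as the table of grain fungi in 17952 of 17952 cells, exactly and with fungal genus names, so grain bacteria, and with them the inoculated Lactobacillus, were not analysed here.

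The fungal table had 544 entries, 457 of them with a genus name, in 33 libraries of 37308 to 74936 reads (median 71762). The cecal table had 399 entries, 251 with a genus name, in 12 libraries of 30871 to 68800 reads (median 53939). Entries without a genus name (unclassified, uncultured) held 1.92% to 41.6% of the reads of a fungal library (median 6.78%) and 29.6% to 55.0% of a cecal library (median 44.5%). They stayed in the library totals and in the fits and were not counted as genera. Entries that name no taxon below the kingdom held 0.803% to 19.1% of a fungal and 0.0298% to 1.63% of a cecal library. Libraries of the same group differed by more than read sampling, with a chi-square per degree of freedom of 23.2 to 600 over 33 pairs of fungal libraries and 127 to 554 over 12 pairs of cecal libraries.

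Shares are percentages of all reads of a library, given as means over 3 libraries, with the SD after ±. Genera were tested with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on the counts, with TMM scaling and a single fit per table over all of its libraries, after leaving out entries with a mean share under 0.01% over the table. This left 222 fungal entries (185 named genera) and 133 cecal entries (87 named genera), and removed at most 2.80% and 4.65% of the reads of a library. P-values were adjusted by Benjamini-Hochberg over the entries tested, and a genus was called changed at an adjusted p under 0.05. A contrast over more than 2 groups is not defined in this fit for an entry with a group of 0 reads on each side, and its p then lies near 1. This held for 141 of 222 entries in the average over the 4 days, which left 81. It held for 7 of 133 entries in the average over the 3 alcohol groups. With such a group on a single side, the fitted log2 fold change has no bound and can rest mostly on that group. Where all libraries of a group had no read of a genus, a fold is a lower bound against 3 counts per library. With 1 to 3 reads in a group, the ratio has a 95% exact Poisson interval. Reads copied by PCR are not independent molecules, so these intervals and floors cover counting error only.

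Shares are relative, so a fitted fold depends on the scaling. The median over all entries of the shift in log2 fold change, TMM minus library totals alone, is given here. In pretreated against control grain it was 0.74 on day 0, -0.15 on day 4, 0 on day 13 and -0.64 on day 26. For the average over these days it was -0.20. The shift was 1.46 on day 3 and 1.99 on day 7 of pretreatment, 0.02 from day 0 to day 26 in control grain and -1.12 in pretreated grain. In the cecum it was 0.51 for control liquor, 0.16 for pretreated liquor, -0.03 for edible alcohol and 0.17 for the average of these 3 groups against water, -0.22 between both liquors, and 0.41 and 0.19 for control and pretreated liquor against alcohol. These medians include entries with few or no reads in both groups, whose folds hardly move with the scaling, so genera with many reads can shift by more. The TMM factors were 4.70 to 5.36 on day 0 and 0.452 to 0.739 on day 7 of pretreatment. Fitted changes are relative to the TMM factors, and folds of shares are not scaled.

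Shannon diversity (natural logarithm, over entries) and list shares were compared by two-sided exact permutation tests, and community composition by exact permutation (PERMANOVA) on Bray-Curtis dissimilarity of shares. With 3 libraries against 3 the smallest p is 0.1, so none of the pairwise permutation tests could pass. Pooled exact tests reach lower: permuting within the 4 days (160000 arrangements, smallest p 1.25e-05), over the 4 gavage groups (15400 partitions) and for the 3 alcohol groups against water (220 arrangements, smallest p 0.00455). The pooled families were adjusted by Benjamini-Hochberg over 15 tests for grain (Shannon diversity, 4 lists and the 10 most abundant genera) and 22 tests for each cecal contrast (Shannon diversity, 11 lists and the 10 most abundant genera). Tests over the 4 days, by permutation, regrouping or edgeR's average, treat the days as independent. The days may be repeated samples of the same fermentations, and the p-values would then be too small. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

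The comparisons, the pairwise tests, the alternatives, the lists and the rule for named genera were fixed before the data were examined. The named genera are the 10 most abundant per table, Lactobacillus in the cecum, the called genera with the 10 largest fitted changes in each direction and a share of at least 0.1% in a group, and up to 4 members of each list. The fungal lists are fermenting yeasts, starter moulds, field fungi of cereals and other yeast-like fungi. The cecal lists are the Muribaculaceae group, other Bacteroidales, Lachnospiraceae and Oscillospiraceae, lactobacilli and bifidobacteria, Erysipelotrichales, the mucin degrader Akkermansia, sulfate reducers, enterobacteria, Helicobacter and Campylobacter, and genera of grain fermentation. The list named Lachnospiraceae and Oscillospiraceae also holds other Clostridia, such as unclassified_Clostridia_UCG_014 and Ruminococcus, so its share is not that of these families alone. The pooled tests, the averages over the 4 days and over the 3 alcohol groups, a list of water and soil bacteria applied to the cecum, library totals as scaling and limma as a model were chosen after the data were seen.

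Alternatives were no filter, DESeq2 1.42.0, leaving out unnamed entries or the most abundant genus, the library number as a block, library totals as scaling, limma 3.58.1 on log2(share in percent + 0.01), other diversity measures, square-root shares for Bray-Curtis, and leaving out each library. The tests were tried on simulated counts drawn from the real library sizes and table-wide mean shares, the same in all groups before any change. Only genera of intermediate mean share were changed, so recovery of the most abundant and the rarest genera was not tried. For pretreated against control grain on day 13 (222 entries), edgeR recovered 0% of genera changed 8-fold, 27.5% of those changed 64-fold and 33.8% of those changed 512-fold. For pretreated liquor against water (133 entries) it recovered 0%, 16.2% and 66.2%. With no genus changed, edgeR made 0 false calls per simulation in both comparisons, DESeq2 19.6 and 2.2, and limma 0.3 and 0.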

Results

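Fungal communities were measured in 33 libraries of fermenting barley grain, with 3 libraries for each of 11 groups, and bacterial communities in 12 libraries of mouse cecal contents, with 3 for each of 4 gavage groups. Library totals lay between 37308 and 74936 reads for fungi and between 30871 and 68800 reads for the cecum. The grain comparisons ask how a fermentation that follows pretreatment differs from a control fermentation, and how fungi change during pretreatment and during fermentation. The cecal comparisons ask how gavage with either liquor differs from water and from edible alcohol.

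On day 0 of formal fermentation, Mucor, a mould that breaks down starch, made up 9.42% ± 1.13 of reads (SD, n = 3) in pretreated grain and 0.0192% ± 0.0333 in control grain, a 490-fold difference. All 38 control reads were in control replicate 2, and without that library the difference was at least 2100-fold. Rhizopus, another starch-degrading mould, stood at 10.5% ± 6.07 against 0.124% ± 0.0328 (84.8-fold), the yeast Candida at 1.49% ± 0.698 against 0.0353% ± 0.0364 (42.2-fold), and the red yeast Rhodotorula at 0.492% ± 0.196 against 0.00408% ± 0.00470 (121-fold). Alternaria, a fungus of cereals in the field, was lower in pretreated grain at 0.138% ± 0.104 against 8.52% ± 7.62. The starter mould Aspergillus was 9.27% ± 0.677 in pretreated and 14.9% ± 1.97 in control grain and did not pass (edgeR adjusted p of 1). Without control replicate 1, Candida was 89.5-fold higher and Alternaria 35.6-fold lower, without control replicate 3 Rhodotorula, with 2 control reads left, was 325-fold higher (counting interval from 91.9 to 2740), and without pretreated replicate 2 Alternaria was 98.4-fold lower. Saccharomyces, the main alcohol-forming yeast, was 45.2% ± 3.72 in pretreated and 43.9% ± 3.26 in control grain and did not pass the test (edgeR adjusted p = 0.725).

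In edgeR's test on day 0, 4 genera rose and 1 fell: Mucor (log2 fold change 9.86 ± 1.37 SE, adjusted p = 1.2e-10), Rhizopus (7.62 ± 1.31, 4.33e-07), Candida (6.24 ± 1.38, 3.47e-04), Rhodotorula (7.94 ± 1.87, 9.86e-04) and Alternaria (-5.12 ± 1.47, 0.0179). Each of the 5 lay beyond the control mean in 3 of 3 pretreated libraries. Of the lists, 2 of 7 tested starter moulds rose, 1 of 10 fermenting yeasts rose, 1 of 5 other yeast-like fungi rose and 1 of 10 field fungi fell, with the same counts adjusted over the list alone (2, 1, 1 and 1). The summed share of starter moulds was 30.2% ± 3.73 against 15.3% ± 1.89, and that of field fungi 1.93% ± 0.375 against 14.3% ± 7.35 (exact permutation p = 0.1 for either, the smallest possible). DESeq2 called 16 genera (7 higher and 9 lower) and limma 8 (5 higher and 3 lower). The Alternaria call was lost without control replicate 1 (adjusted p = 0.211) or pretreated replicates 1, 2 or 3 (0.158, 0.0533 and 0.204), where its log2 fold change lay between -5.88 and -4.31, and with unnamed entries left out (0.197).

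On day 4, Mucor reached 11.3% ± 1.28 in pretreated grain, while the 3 control libraries together held a single read of it. The ratio was 23085, with a counting interval from 4388 to 965686, and without control replicate 1, which held that read, Mucor was at least 2792-fold higher. Rhodotorula was 0.0357% ± 0.0205 in pretreated grain and had 0 reads in control grain, at least 8.58-fold higher. Candida was 14.6% ± 5.61 against 1.33% ± 1.79 and Saccharomyces 59.8% ± 4.18 against 87.4% ± 4.28, and neither passed the test on this day alone (edgeR adjusted p = 0.401 and 0.641).

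Mucor (edgeR adjusted p = 4.33e-15) and Rhodotorula (0.0169) rose on day 4 and 0 genera fell, with 11 named genera at an unadjusted p under 0.05. Mucor and Rhodotorula were above the control mean in 3 of 3 libraries. These were 1 of 7 starter moulds and 1 of 5 other yeast-like fungi, with 0 of 10 fermenting yeasts and 0 of 10 field fungi called, and the counts adjusted over the list alone were the same (1, 1, 0 and 0). Summed shares were 13.1% ± 0.984 against 3.57% ± 1.22 for starter moulds and 75.5% ± 6.13 against 89.1% ± 2.19 for fermenting yeasts (exact permutation p = 0.1 for either). DESeq2 called 17 genera (10 higher and 7 lower) and limma 2. The Rhodotorula call was lost without control replicates 1, 2 or 3 (adjusted p = 0.113, 0.218 and 0.188), with no filter (0.0658), with DESeq2 (0.0650), with limma (adjusted p of 1) and with unnamed entries left out (0.104).

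On day 13, Pichia, a yeast known for forming esters, made up 14.1% ± 3.86 of pretreated grain and 0.256% ± 0.238 of control grain, 55.1-fold higher. Mucor stood at 1.39% ± 0.865 against 0 reads, at least 341-fold higher, and Rhizopus at 0.183% ± 0.187 against 0.00314% ± 0.00431 (58.1-fold). Wickerhamomyces, a yeast that forms ethyl acetate, had 1 read in pretreated grain and 0.156% ± 0.0831 in control grain, a ratio of 334 with a counting interval from 57.1 to 12574. Epicoccum, a fungus of plant surfaces, had 0 reads in pretreated grain and 0.983% ± 1.62 in control grain, at least 221-fold lower. Without control replicate 2, Epicoccum was at least 11.2-fold lower. Rhizopus was 26.6-fold higher without pretreated replicate 3 and, with 1 control read left, 268-fold without control replicate 3 (counting interval from 47.9 to 10530), Pichia 118-fold without control replicate 1, and Mucor at least 221-fold without pretreated replicate 2. Without pretreated replicate 3, which held the single read, Wickerhamomyces was at least 34.3-fold lower.

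These 5 genera passed edgeR's test on day 13, with 3 higher (Mucor, adjusted p = 9.34e-13; Rhizopus, log2 5.05 ± 1.18, 0.00112; Pichia, 5.53 ± 1.40, 0.00297) and 2 lower (Wickerhamomyces, 2.34e-04; Epicoccum, 2.81e-04), each in 3 of 3 libraries. Among the lists, 2 of 7 starter moulds rose, 1 of 10 fermenting yeasts rose and 1 fell, 1 of 10 field fungi fell and 0 of 5 other yeast-like fungi were called. Adjusted over the list alone, 1 starter mould also fell and the other counts did not move. Summed shares were 80.7% ± 12.0 against 84.2% ± 1.17 for fermenting yeasts and 2.53% ± 0.961 against 4.14% ± 1.40 for starter moulds (exact permutation p = 0.9 and 0.2). DESeq2 called 37 genera (16 higher and 21 lower) and limma 3 (2 higher and 1 lower). The Pichia call was lost without control replicate 2 (adjusted p = 0.0614) or 3 (0.0588) and with no filter (0.0505), that of Rhizopus without pretreated replicate 3 (log2 3.30, 0.130) and with limma (0.199), and that of Epicoccum without control replicate 2 (0.136) and with limma (0.350), where 3 genera were left without control replicate 2.

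By day 26, Mucor was 2.99% ± 1.28 in pretreated grain, with 3 reads in the control libraries, a ratio of 2222 with a counting interval from 747 to 10587. Wickerhamomyces had 0 reads in pretreated grain and 0.0994% ± 0.113 in control grain, at least 22.9-fold lower. Without control replicate 3, Mucor was at least 721-fold higher and Wickerhamomyces at least 8.06-fold lower. Glarea, a genus known for producing antifungal lipopeptides, was 0.00598% ± 0.0104 against 0.181% ± 0.116 (30.2-fold lower). Saccharomyces was 54.9% ± 22.4 against 78.8% ± 9.23 and Pichia 6.41% ± 7.45 against 1.53% ± 2.47, with a wide spread between libraries, and neither passed.

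In edgeR's test on day 26, Mucor rose (adjusted p = 2.07e-10) and Wickerhamomyces (8.43e-06) and Glarea (log2 fold change -6.48 ± 1.76 SE, 0.0177) fell, each in 3 of 3 libraries. They were 1 of 7 starter moulds and 1 of 10 fermenting yeasts, Glarea belonging to no list, with 0 of 10 field fungi and 0 of 5 other yeast-like fungi called and the same counts adjusted over the list alone (1, 1, 0 and 0). Summed shares were 62.2% ± 24.9 against 80.6% ± 6.95 for fermenting yeasts, 5.56% ± 1.36 against 5.42% ± 1.40 for starter moulds and 0.675% ± 0.148 against 0.490% ± 0.130 for other yeast-like fungi. DESeq2 called 19 genera (9 higher and 10 lower), limma 3 (2 higher and 1 lower) and library totals as scaling 2 (1 higher and 1 lower). The Glarea call was lost without pretreated replicate 1 (adjusted p = 0.195) or 2 (0.290), with library totals (0.479), no filter (0.196), unnamed entries left out (0.116) or Saccharomyces left out (0.116), and that of Wickerhamomyces with limma (0.0558).

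Over the 4 days together, Saccharomyces averaged 56.3% in pretreated and 73.4% in control grain, a lower share in pretreated grain. Mucor was 6.27 percentage points higher, Candida 4.06 points, Pichia 4.88 points and Rhizopus 2.69 points, while Aspergillus, the starch-degrading mould of the control grain, averaged 3.28% against 6.84% and Filobasidium, a yeast of leaf surfaces, 0.116% against 0.516%. Mucor, Candida and Aspergillus lay on their side of the same day's control mean in 12 of 12 pretreated libraries, Filobasidium in 11, Saccharomyces and Rhizopus in 10, and Pichia in 8. Shannon diversity was 2.08, 1.57, 1.60 and 2.26 in pretreated grain on days 0, 4, 13 and 26, against 2.25, 0.768, 0.989 and 1.20 in control grain.

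In exact permutation tests within days, Mucor, Candida and Aspergillus reached the smallest p the arrangements allow (1.25e-05, adjusted 6.25e-05). These tests treat the 4 days as independent, although they may be repeated samples of the same fermentations. Rhizopus (adjusted p = 0.00108), Saccharomyces (-17.1 points, 0.00405), Filobasidium (-0.399 points, 0.00506) and Pichia (0.0125) also passed by exact permutation. Fusarium, Alternaria and Cladosporium, fungi of cereals in the field, differed by 0.256, -1.75 and 0.217 points and did not pass (exact permutation, adjusted p = 0.445, 0.411 and 0.896), and without pretreated day 4 replicate 2 or pretreated day 26 replicate 3 the difference of Cladosporium was -0.213 or -0.0803. It ran from -0.213 to 0.635 without each library in turn, that of Fusarium from 0.0835 (without pretreated day 26 replicate 3) to 0.363, being 0.161 without pretreated day 13 replicate 2, and that of Alternaria from -2.75 (without control day 0 replicate 3) to -0.854 (without control day 0 replicate 1). Of the lists, starter moulds rose by 5.77 points (adjusted p = 0.00921, exact permutation, 7 of 12 libraries) and fermenting yeasts fell by 9.08 points (0.0394, 8 of 12), while field fungi (-2.33 points, 0.340) and other yeast-like fungi (0.103 points, 0.340) did not pass. Without pretreated day 26 replicate 3 the difference of fermenting yeasts was -5.57 points, and without pretreated day 0 replicate 2 that of other yeast-like fungi 0.0624 points. The adjusted p of fermenting yeasts lay between 0.0509 and 0.124 (exact permutation) when any of these libraries was left out: control day 0 replicate 3, control day 4 replicates 2 and 3, control day 13 replicates 1, 2 and 3, control day 26 replicates 1, 2 and 3, pretreated day 0 replicate 3, pretreated day 4 replicates 1 and 2, pretreated day 13 replicate 2 or pretreated day 26 replicate 3. Leaving out unnamed entries gave 0.0572.

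Shannon diversity was 0.573 higher in pretreated grain by the pooled exact permutation test (adjusted p = 0.00984), with 9 of 12 libraries above the same day's control mean. The difference reversed to -0.399 with Saccharomyces left out and to -1.92 when entries above 0.01% were counted instead. Single days gave differences of -0.170, 0.803, 0.607 and 1.05 (exact permutation p = 0.3, 0.1, 0.1 and 0.2). Without each library in turn these ran from -0.255 to -0.0390, 0.729 to 0.929, 0.274 to 0.822 and 0.501 to 1.53. The value nearest 0 came without control replicate 2 on day 0, pretreated replicate 2 on day 13 and pretreated replicate 3 on day 26, whose Shannon diversity was 3.36 with 34.1% fermenting yeasts, against 2.10 and 1.31 with 70.6% and 81.8% in the other libraries of its group. Pretreated and control communities differed within days on Bray-Curtis dissimilarity (R2 = 0.568, exact permutation p = 0.0002), again with the days taken as independent. Single days gave R2 of 0.710, 0.836, 0.634 and 0.312 (exact permutation p = 0.1, 0.1, 0.1 and 0.2).

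Averaged over the 4 days in edgeR's fit, 6 genera rose and 4 fell, out of 81 entries for which this average was defined. Mucor (adjusted p = 4.74e-50), Rhizopus (log2 fold change 3.55 ± 0.55 SE, 6.98e-09), Candida (3.46 ± 0.60, 6.3e-07), Pichia (2.31 ± 0.61, 0.00385), Rhodotorula (7.28e-04) and Trichomerium (0.0115) rose. Wickerhamomyces (7.28e-10), Epicoccum (0.00250), Glarea (-2.91 ± 0.75, 0.00311) and Aspergillus (-1.70 ± 0.49, 0.0123) fell. Trichomerium lay above the same day's control mean in only 6 of 12 libraries and Rhodotorula in 8. Some groups had no reads: Mucor in control grain on day 13, Rhodotorula in control grain on day 4, Wickerhamomyces in pretreated grain on day 26 and Epicoccum in pretreated grain on day 13. The fitted average of these genera has no bound and can rest mostly on that day. Rhodotorula was lower in pretreated grain on day 13 (0.0111% against 0.0274%). By list, 2 of 7 starter moulds rose and 1 fell, 2 of 10 fermenting yeasts rose and 1 fell, 1 of 5 other yeast-like fungi rose and 1 of 10 field fungi fell, and adjusted over the list alone 3 starter moulds rose and 4 field fungi fell. DESeq2 called 26 genera (9 higher and 17 lower), limma 9 (4 higher and 5 lower) and library totals 8 (6 higher and 2 lower).

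Some of these averaged edgeR calls were lost in single fits. Aspergillus was lost without pretreated day 26 replicate 3 (log2 fold change -1.58, adjusted p = 0.0522) and with unnamed entries left out (0.0977). Epicoccum was lost without control day 13 replicate 2 (0.209), with library totals (0.0524) and with limma (0.856), and Glarea with library totals (0.142). Rhodotorula was lost without pretreated day 13 replicate 1 or pretreated day 26 replicate 1, where pretreated grain of that day, like control grain on day 4, had 0 reads left and the average was no longer defined. It was also lost with DESeq2 (0.0572), with the library number as a block (0.0889) and with limma (0.552). Trichomerium was lost without pretreated day 0 replicate 2 or pretreated day 26 replicate 3, where the average was again not defined, and with limma (0.853).

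**Figure D1:**
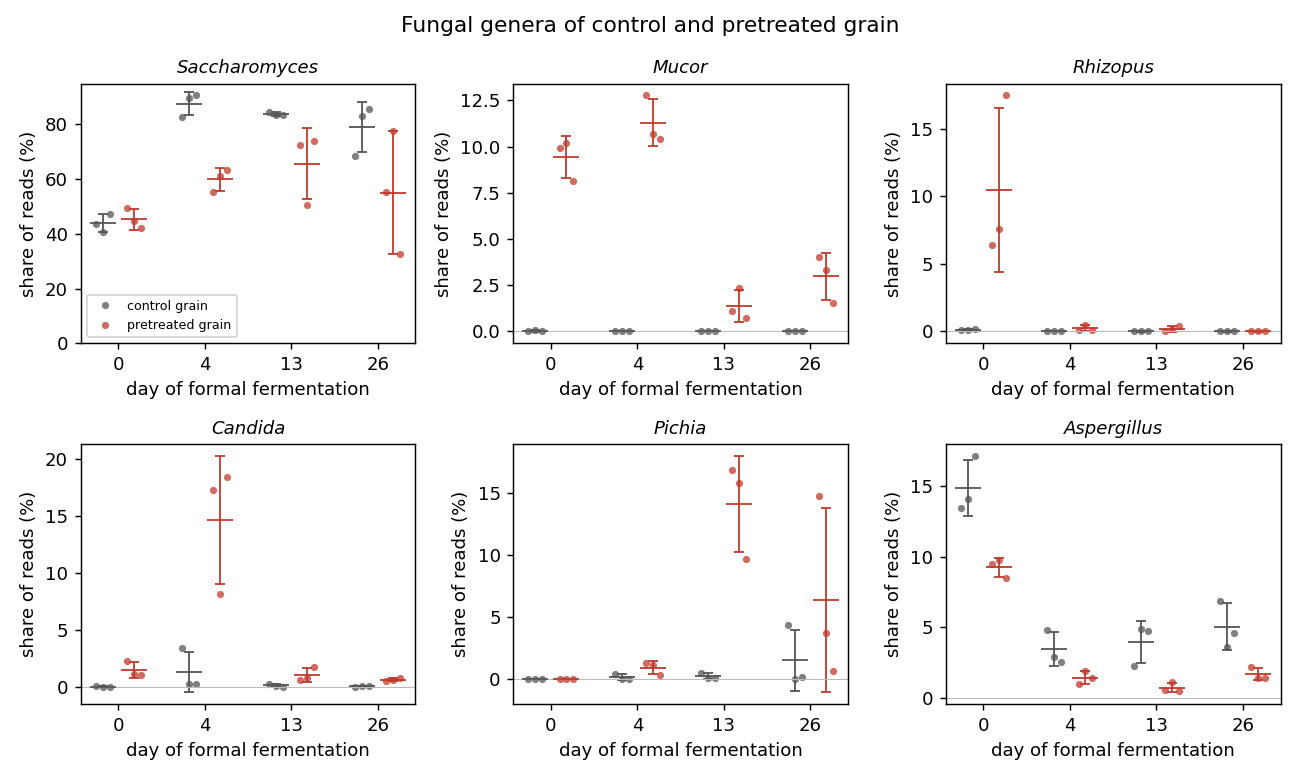
Share of reads in percent (vertical axes) of fungal genera by day of formal fermentation (horizontal axis) in control and pretreated grain; points are libraries, horizontal marks the mean and bars the SD (n = 3). Mucor averaged 11.3% in pretreated grain on day 4 and Saccharomyces 87.4% in control grain on that day.

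During pretreatment, Mucor rose from 0 reads on day 0 to 40.6% ± 28.7 on day 3, at least 6854-fold higher. Rhodotorula reached 4.88% ± 4.04 against 0.162% ± 0.280 (30.2-fold), and the yeasts Candida (0.0196% ± 0.0219) and Wickerhamomyces (0.0168% ± 0.0151) appeared at shares at least 3.30-fold and 2.84-fold above the limit for 0 reads on day 0. Rhizopus had 0 reads on day 3 after 0.181% ± 0.311 on day 0, at least 40.2-fold lower. Day 0 replicate 3 held 0.540% Rhizopus, and without it the share on day 0 was 0.298 times the limit for 0 reads, so no fall could be seen. Starter moulds together made up 43.3% ± 28.0 on day 3 and 3.89% ± 0.611 on day 0, and field fungi 20.5% ± 7.69 and 24.0% ± 4.77, with sums not tested here. Day 3 replicate 1 stood apart from replicates 2 and 3, with 7.44% Mucor against 55.4% and 58.8%, 11% starter moulds against 57.9% and 61.0%, 29.4% field fungi against 15.9% and 16.3%, a Shannon diversity of 3.67 against 2.13 and 1.97, and a TMM factor of 4.19 against 0.788 and 1.25, the factors on day 0 being 4.70 to 5.36. Without day 3 replicate 2, Candida and Wickerhamomyces were at least 1.30-fold and 1.78-fold above the limit, and without day 0 replicate 1, which held all reads of Rhodotorula on day 0, that genus was at least 1005-fold higher.

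In edgeR's test of day 3 against day 0, Mucor (adjusted p = 3.64e-23), Candida (4.18e-06), Wickerhamomyces (1.16e-04) and Rhodotorula (log2 fold change 7.35 ± 1.82 SE, 0.00195) rose and Rhizopus fell (9.24e-07), with Candida and Wickerhamomyces seen in 2 of 3 libraries. By list, 1 of 7 starter moulds rose and 1 fell, 2 of 10 fermenting yeasts rose, 1 of 5 other yeast-like fungi rose and 0 of 10 field fungi were called, and adjusted over the list alone 2 other yeast-like fungi rose. DESeq2 called 26 genera (15 higher and 11 lower) and limma 9 (4 higher and 5 lower). The call of Rhodotorula was lost without day 0 replicate 2 (adjusted p = 0.0549) or 3 (0.18) or day 3 replicate 2 (0.0554), with library totals (0.248), no filter (0.105) or unnamed entries left out (0.0642). That of Rhizopus was lost without day 0 replicate 3 (0.501), where 3 genera were called, and with limma (0.213), as were those of Candida (0.396) and Wickerhamomyces (0.281) with limma.

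On day 7 of pretreatment, 3 moulds made up most reads on average: Mucor with 28.6% ± 22.2, Rhizopus with 28.4% ± 34.4 and Aspergillus with 19.3% ± 28.9. Each was highest in a different library, Mucor in replicate 1, Rhizopus in replicate 2 and Aspergillus in replicate 3, so these means describe no single library. Against day 0, Mucor was at least 4840-fold higher, Rhizopus 157-fold and Aspergillus 9.56-fold, and the starter moulds summed to 78.2% ± 8.31. Aspergillus was 1.29-fold higher without day 7 replicate 3. Rhizopus was 47.4-fold higher without day 7 replicate 2 and, with 1 read left on day 0, 21206-fold without day 0 replicate 3 (counting interval from 5127 to 1.13e+06), and Mucor at least 2739-fold without day 7 replicate 1. Candida (0.326% ± 0.137) was at least 55.1-fold and Wickerhamomyces (0.0162% ± 0.0118) at least 2.74-fold above the limit for 0 reads on day 0. Saccharomyces was 5.73% ± 0.630 on day 7 and 3.77% ± 3.47 on day 0 (1.52-fold higher, and 3.23-fold without day 0 replicate 1), and field fungi were 2.19% ± 1.22 and 24.0% ± 4.77, with 0 of 10 members called.

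All 6 named genera rose on day 7 against day 0 in edgeR's test: Mucor (adjusted p = 1.66e-23), Candida (6.74e-11), Rhizopus (7.39e-11), Aspergillus (log2 fold change 6.71 ± 1.23 SE, 2.69e-06), Wickerhamomyces (2.54e-05) and Saccharomyces (3.88 ± 0.90, 5.42e-04). They were 3 of 7 starter moulds and 3 of 10 fermenting yeasts, with 0 of 5 other yeast-like fungi, of which 2 rose adjusted over the list alone. Library totals as scaling gave 7 genera (5 higher and 2 lower), DESeq2 27 (14 higher and 13 lower) and limma 17 (3 higher and 14 lower). Saccharomyces was not called with library totals (log2 0.61, adjusted p = 0.585) or limma (0.484). Aspergillus, above the day 0 mean in 2 of 3 libraries, was not called without day 7 replicate 3 (log2 3.36, 0.0877) or with limma (0.166), and Wickerhamomyces not with limma (0.317).

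**Figure D2:**
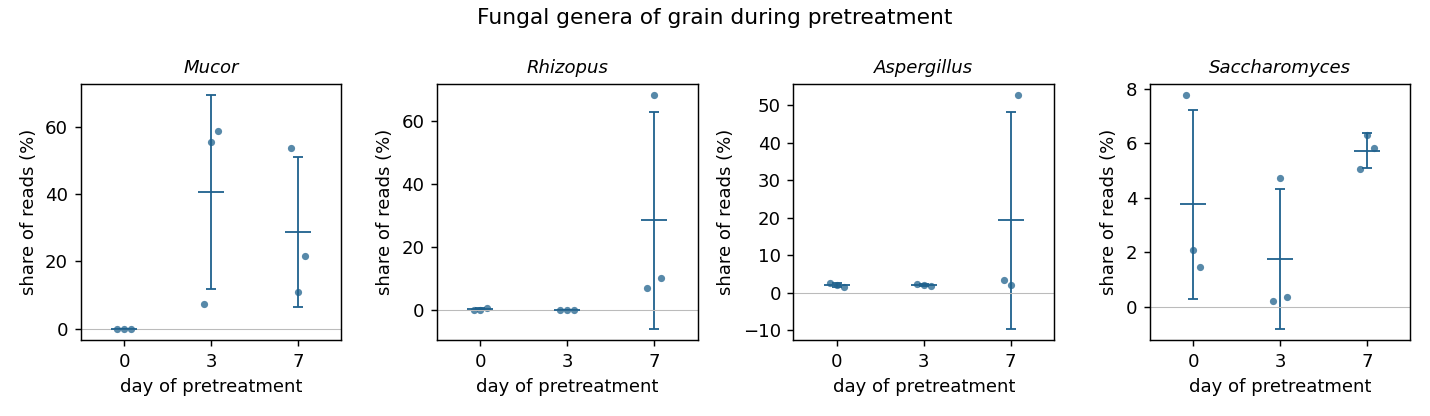
Share of reads in percent (vertical axes) of fungal genera in grain on days 0, 3 and 7 of pretreatment (horizontal axis); points are libraries, horizontal marks the mean and bars the SD (n = 3). Mucor averaged 40.6% on day 3 and Rhizopus 28.4% on day 7, with a wide spread between libraries.

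From day 0 to day 26 of the control fermentation, Wickerhamomyces went from 7.11% ± 0.840 to 0.0994% ± 0.113 (71.6-fold lower) and Alternaria from 8.52% ± 7.62 to 0.145% ± 0.0785 (58.8-fold lower). Cystofilobasidium, a cold-tolerant yeast, went from 0.208% ± 0.0412 to 0 reads, at least 50.7-fold lower. Pichia was 0.0479% ± 0.0255 on day 0 and 1.53% ± 2.47 on day 26 (32.0-fold higher), above the day 0 mean in 2 of 3 libraries. Pichia was 2.19-fold higher without day 26 replicate 1, Alternaria 34.1-fold lower without day 0 replicate 1 and Wickerhamomyces 204-fold lower without day 26 replicate 3. Saccharomyces, at 43.9% ± 3.26 and 78.8% ± 9.23, was not called.

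In edgeR's test of control grain, Pichia rose (log2 fold change 4.96 ± 1.37 SE, adjusted p = 0.0310) and Alternaria (-5.53 ± 1.5, 0.0310), Wickerhamomyces (-5.21 ± 1.51, 0.0363) and Cystofilobasidium (0.0363) fell. By list, 1 of 10 fermenting yeasts rose and 1 fell, 2 of 10 field fungi fell, and 0 of 7 starter moulds and 0 of 5 other yeast-like fungi were called, while adjusted over the list alone 2 starter moulds fell and 1 other yeast-like fungus rose. DESeq2 called 20 genera (3 higher and 17 lower) and limma 5 (0 higher and 5 lower). No filter, like unnamed entries left out, gave 0 (23 and 13 named genera at an unadjusted p under 0.05). The edgeR count was 0 without day 0 replicate 1 or day 26 replicate 1, 1 without day 0 replicate 3, 2 without day 26 replicate 2, and 3 without day 0 replicate 2 or day 26 replicate 3. Adjusted p of the lost calls was 0.161 to 0.186 without day 0 replicate 1 and 0.173 to 0.651 without day 26 replicate 1. It was 0.0709 to 0.121 without day 0 replicate 3, 0.249 to 0.313 without day 26 replicate 2, 0.127 for Pichia without day 0 replicate 2, and 0.0714 and 0.179 for Alternaria and Cystofilobasidium without day 26 replicate 3. In these fits the log2 fold change lay between -5.85 and -4.72 for Alternaria and between -5.27 and -4.66 for Wickerhamomyces, while that of Pichia lay between 4.64 and 4.88 except without day 26 replicate 1, where it was 2.11. Pichia was also lost with the library number as a block (0.148) and with limma (0.441).

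In pretreated grain, Pichia was 0.0269% ± 0.00708 on day 0 and 6.41% ± 7.45 on day 26, 238-fold higher. Rhizopus fell from 10.5% ± 6.07 to 0.0238% ± 0.0376 (439-fold lower), Glarea from 1.79% ± 0.128 to 0.00598% ± 0.0104 (299-fold lower), Aspergillus from 9.27% ± 0.677 to 1.68% ± 0.432 (5.51-fold lower), and Wickerhamomyces from 3.49% ± 0.535 to 0 reads, at least 805-fold lower. Pichia was 81.7-fold higher without day 26 replicate 1, and Rhizopus, with 3 reads left on day 26, 4977-fold lower without day 26 replicate 3 (counting interval from 1684 to 23861). Mucor, at 9.42% ± 1.13 on day 0 and 2.99% ± 1.28 on day 26, was not called (edgeR adjusted p = 0.133).

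In edgeR's test of pretreated grain, 1 genus rose (Pichia, log2 fold change 6.73 ± 1.48 SE, adjusted p = 2.59e-04) and 4 fell (Rhizopus, -11.05 ± 1.5, 3.78e-11; Wickerhamomyces, 3.9e-10; Glarea, -10.35 ± 2.07, 3.3e-05; Aspergillus, -3.70 ± 1.07, 0.0190), each in 3 of 3 libraries. By list, 2 of 7 starter moulds fell, 1 of 10 fermenting yeasts rose and 1 fell, and 0 of 10 field fungi and 0 of 5 other yeast-like fungi were called, while adjusted over the list alone 3 starter moulds and 1 other yeast-like fungus fell. DESeq2 called 22 genera (6 higher and 16 lower) and limma 7 (3 higher and 4 lower). Aspergillus was not called without day 0 replicate 3 (adjusted p = 0.0560) or day 26 replicates 1, 2 or 3 (0.101, 0.0628 and 0.245), with library totals (0.300), unnamed entries left out (0.142) or limma (0.0884). Whether the time courses of control and pretreated grain differ is a question of the difference between their changes, which is treated with the interaction of day and pretreatment.

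In the cecum, the gut bacteria Alloprevotella (11.7% ± 8.60 in water, 14.3% ± 15.7 in alcohol, 7.75% ± 8.23 in control liquor and 12.0% ± 11.5 in pretreated liquor) and Bacteroides (9.28% ± 1.10, 8.53% ± 4.26, 8.79% ± 5.45 and 6.55% ± 4.54), both known to degrade polysaccharides, and the Lachnospiraceae_NK4A136_group (9.47% ± 3.29, 7.88% ± 9.42, 12.0% ± 1.63 and 5.0% ± 1.39) were the most abundant named genera in the mean over all groups. In pretreated liquor, Escherichia_Shigella averaged 8.36%, above Bacteroides and the Lachnospiraceae_NK4A136_group. For the next genera the groups are in the same order. Alistipes held 2.15% ± 0.710, 3.75% ± 1.36, 2.39% ± 0.229 and 3.27% ± 1.34, Erysipelatoclostridium 1.27% ± 2.01, 2.36% ± 2.07, 1.84% ± 1.42 and 1.24% ± 0.994, Odoribacter 1.97% ± 1.56, 2.42% ± 3.63, 1.41% ± 1.54 and 0.426% ± 0.207, and Quinella 2.75% ± 2.48, 0.967% ± 0.977, 0.0112% ± 0.0166 and 1.23% ± 1.93 in the same order. Helicobacter, a spiral bacterium of mucus, was 3.56% ± 1.55 after water, 1.37% ± 0.953 after alcohol, 0.146% ± 0.192 after control liquor and 1.06% ± 1.04 after pretreated liquor. Lactobacillus, a genus of lactic acid bacteria, was 0.0791% ± 0.101, 1.78% ± 2.52, 0.862% ± 0.764 and 1.65% ± 1.96.

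Escherichia_Shigella, facultative anaerobes of the gut, rose after pretreated liquor against water, from 0.00362% ± 0.00627 (5 reads in 3 libraries) to 8.36% ± 9.41, 2309-fold. The 3 pretreated liquor libraries held 6.50%, 18.6% and 0.0289% of it, all above the water mean, and without replicate 2 the difference was 901-fold. It was the only genus called (edgeR log2 fold change 11.90 ± 2.53 SE, adjusted p = 0.0110), with 10 named genera at an unadjusted p under 0.05. DESeq2 called 3 genera and limma 0. The call was lost with limma (adjusted p = 0.0680) and without water replicate 2 (edgeR adjusted p = 0.176), the library that held all 5 reads. Without that library the difference was at least 1131-fold and the SE of the fitted log2 fold change went from 2.53 to 3.93. Water replicate 2 stood apart, with reads in 181 entries against 99 and 90 in the other water libraries and a TMM factor of 2.28 against 0.804 and 0.935. Pretreated liquor replicate 2 had reads in 218 entries, against 125 and 96 in its group.

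Against water, edgeR called 0 genera after control liquor (11 named genera at an unadjusted p under 0.05, 4 called by DESeq2 and 0 by limma). After edible alcohol it also called 0 (10 named genera at an unadjusted p under 0.05, 4 called by DESeq2 and 0 by limma). After control liquor, Quinella was 245.5-fold lower, Escherichia_Shigella 97.4-fold higher, Ligilactobacillus 36.2-fold higher and Helicobacter 24.4-fold lower than after water, and none of these 4 passed edgeR's test (adjusted p = 0.195, 0.195, 0.234 and 0.270). Without control liquor replicate 2, Helicobacter was 97.2-fold lower, Escherichia_Shigella 64.7-fold higher and Quinella, with 2 reads left, 1660-fold lower (counting interval from 430 to 12814). Quinella was 124-fold lower without water replicate 1, Ligilactobacillus 23.5-fold higher without control liquor replicate 1 and 83.0-fold without water replicate 2, and Escherichia_Shigella at least 47.7-fold higher without water replicate 2. After alcohol, Escherichia_Shigella was 53.5-fold and Lactobacillus 22.4-fold higher than after water and neither passed (edgeR adjusted p = 0.211 and 0.292). Lactobacillus was 4.09-fold higher without alcohol replicate 1 and 80.8-fold without water replicate 2, and Escherichia_Shigella at least 26.2-fold higher without water replicate 2. Counts after control liquor were 2 without its replicate 2, 1 without its replicate 3 and 4 without water replicate 3. Counts after alcohol were 1 without water replicate 1 or alcohol replicate 3, and 2 without water replicate 3 or alcohol replicate 2. With no filter 2 and 1 genera, and with unnamed entries left out 2 and 3 genera, passed for control liquor and alcohol.

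Between both liquors edgeR called 0 genera (10 named genera at an unadjusted p under 0.05, DESeq2 and limma 0). Against alcohol it called 0 after control liquor (7 named genera at that level, DESeq2 and limma 0) and 0 after pretreated liquor (7, DESeq2 and limma 0). Escherichia_Shigella was 23.7-fold higher after pretreated than after control liquor and 43.2-fold higher than after alcohol, without passing edgeR's test (adjusted p = 0.513 and 0.382). The direction was not shared by all libraries. Pretreated liquor replicate 3 (0.0289%) lay below all control liquor libraries (0.143%, 0.590% and 0.326%). It also lay below alcohol replicates 1 and 3 (0.266% and 0.315%) and above alcohol replicate 2, which had no reads of this genus. Quinella was 110-fold higher after pretreated than after control liquor (0.473). Without pretreated liquor replicate 2 Escherichia_Shigella was 9.24-fold higher than after control liquor and 16.8-fold higher than after alcohol, and without control liquor replicate 2 it was 35.7-fold higher than after control liquor. Quinella was 10.5-fold higher without pretreated liquor replicate 1 and, with 2 reads left after control liquor, 741-fold without control liquor replicate 2 (counting interval from 192 to 5722). Against alcohol, control liquor gave 2 calls without its replicate 2 and 1 without alcohol replicate 2 or 3, and pretreated liquor gave 2 without its replicate 3 and 1 without alcohol replicate 2 or 3. With no filter or with unnamed entries left out, 2 genera passed for control liquor and 1 for pretreated liquor against alcohol.

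Over the 3 alcohol groups together against water, Helicobacter was 2.70 percentage points lower, with 9 of 9 libraries below the water mean, and did not pass the correction (exact permutation p = 0.0136, adjusted 0.150). Lactobacillus was 1.35 points higher, in 9 of 9 libraries, and did not pass either (exact permutation p = 0.105, adjusted 0.375). Over the 4 groups, Helicobacter (exact permutation p = 0.0351, adjusted 0.386), Escherichia_Shigella (0.0932, adjusted 0.512) and the other 8 of the 10 most abundant genera did not pass. Without pretreated liquor replicate 3, the library with least Escherichia_Shigella of its group, that genus differed between the 4 groups (exact permutation, adjusted p = 0.025). In edgeR's fit 0 genera were called for the 3 alcohol groups against water (13 named genera at an unadjusted p under 0.05, 4 called by DESeq2 and 0 by limma). The edgeR count was 3 without pretreated liquor replicate 1, 2 without control liquor replicate 3 or water replicate 3, and 1 without control liquor replicate 1 or 2, water replicate 1, alcohol replicate 1 or 2, or pretreated liquor replicate 3. It was 1 with no filter or with Alloprevotella left out, and 5 with unnamed entries left out.

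The list shares of the cecum are given in the order water, alcohol, control liquor and pretreated liquor. The Muribaculaceae group held 10.3% ± 3.06, 12.8% ± 2.35, 13.3% ± 4.67 and 15.3% ± 3.44, and other Bacteroidales 29.1% ± 8.76, 35.1% ± 18.1, 23.2% ± 6.57 and 25.9% ± 15.1. The list named Lachnospiraceae and Oscillospiraceae, with its other Clostridia, held 30.7% ± 7.95, 23.4% ± 12.0, 38.4% ± 5.85 and 25.3% ± 4.58. Lactobacilli and bifidobacteria held 0.134% ± 0.174, 2.47% ± 3.52, 1.94% ± 1.41 and 1.87% ± 2.06, Erysipelotrichales 1.29% ± 2.05, 2.42% ± 2.14, 1.93% ± 1.5 and 1.24% ± 0.997, and sulfate reducers 5.43% ± 3.93, 2.76% ± 2.05, 3.18% ± 2.12 and 2.55% ± 2.19. Genera of grain fermentation held 0.0432% ± 0.0748, 0.589% ± 0.836, 0.0807% ± 0.0524 and 0.741% ± 1.15, the mucin degrader Akkermansia 0.0464% ± 0.0803, 0.0220% ± 0.0382, 0.00381% ± 0.00660 and 0.00291% ± 0.00504, and water and soil bacteria 0.201% ± 0.332, 0.00615% ± 0.0107, 0.00325% ± 0.00294 and 0.0107% ± 0.0185, while enterobacteria and the list of Helicobacter and Campylobacter held only Escherichia_Shigella and Helicobacter. Several means came mostly from 1 library, with 6.54% lactobacilli and bifidobacteria in alcohol replicate 1 against 0.377% and 0.501% in the others, 3.66% Erysipelotrichales in water replicate 1 against 0.0869% and 0.136%, and 0.585% water and soil bacteria in water replicate 2 against 0.00845% and 0.00972%. None of the 11 lists passed over the 4 groups or for the 3 alcohol groups together against water (exact permutation, lowest adjusted p = 0.386 and 0.150). Among list members, edgeR called 1 of 1 enterobacteria after pretreated liquor against water and 0 members of the other lists in any comparison. Adjusted over the list alone, 2 of 3 lactobacilli and bifidobacteria rose after control liquor, 2 after alcohol and 1 after pretreated liquor against water. After alcohol, 1 other Bacteroidales genus and 1 genus of grain fermentation rose and 1 of water and soil bacteria fell. Between both liquors, 1 of Erysipelotrichales was lower after pretreated liquor. Against alcohol, 1 other Bacteroidales genus was lower after either liquor, and after pretreated liquor 1 of Erysipelotrichales was lower. For the 3 alcohol groups against water, 2 lactobacilli and bifidobacteria rose and 1 of water and soil bacteria fell. Lists with 1 tested member (Akkermansia, Escherichia_Shigella and Helicobacter) are left out of these counts, since adjusting over them corrects nothing. Over lists with 2 or 3 tested members it corrects little. These counts are not corrected for the number of lists and comparisons.

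Shannon diversity of the cecum was 3.04 after water, 2.93 after alcohol, 2.90 after control liquor and 3.0 after pretreated liquor and did not differ detectably between the 4 groups (exact permutation p = 0.900). Bray-Curtis dissimilarity gave R2 = 0.270 over the 4 groups (exact permutation p = 0.488) and 0.238, 0.263 and 0.146 for control liquor, pretreated liquor and alcohol against water (exact permutation p = 0.3, 0.4 and 0.8). It was 0.259 between both liquors, and 0.177 and 0.130 for control and pretreated liquor against alcohol (exact permutation p = 0.3, 0.5 and 0.9).

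**Figure D3:**
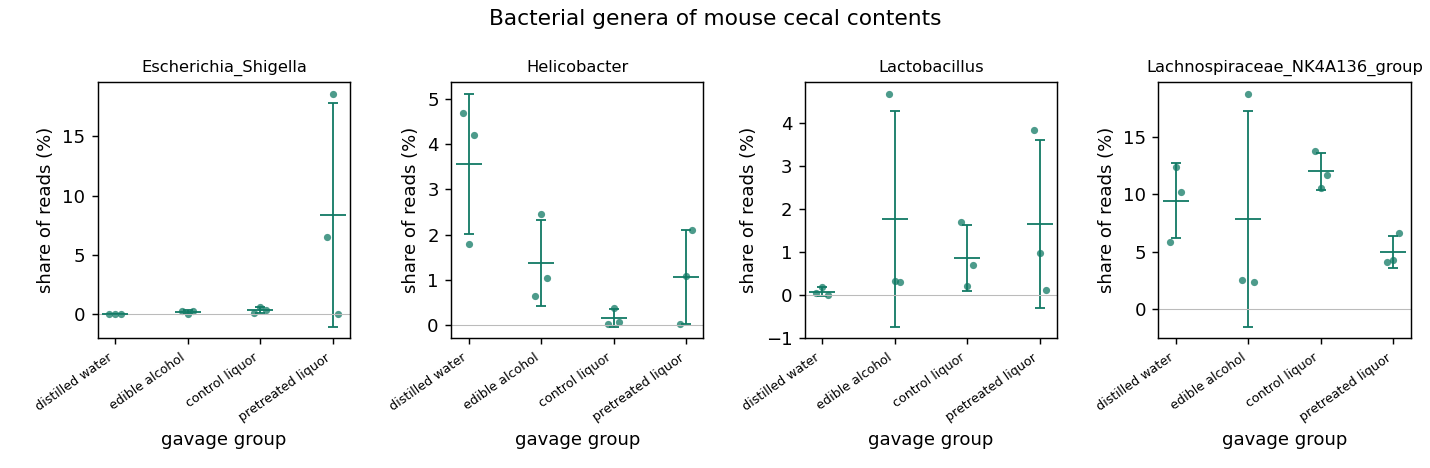
Share of reads in percent (vertical axes) of bacterial genera in mouse cecal contents by gavage group (horizontal axis); points are libraries, horizontal marks the mean and bars the SD (n = 3). Escherichia_Shigella averaged 8.36% after pretreated liquor, from libraries of 6.50%, 18.6% and 0.0289%.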

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

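The tests of differences between days and all tests of explanations were chosen only after the results were seen.

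The effect of pretreatment on several genera differed between day 0 and a later day (edgeR, pretreated minus control at the later day against day 0). Rhizopus was higher in pretreated grain on day 0 (10.5% against 0.124%), and its effect differed on day 4 (0.252% against 0.0355%, log2 difference -5.51 ± 1.48 SE, adjusted p = 0.0241) and on day 26 (0.0238% against 0.0123%, -8.18 ± 1.58, 5.03e-05), while on day 13 it was 0.183% against 0.00314% and the difference from day 0 did not pass (Rhizopus, interaction at day 13, -2.57 ± 1.48, 0.343). Rhodotorula was higher on day 0 (0.492% against 0.00408%), and its effect differed on day 13 (0.0111% against 0.0274%, -8.92 ± 2.26, adjusted p = 0.00900) and day 26 (0.0511% against 0.0429%, -8.88 ± 2.25, 0.00609). On each of these later days, replicate 1 held all Rhodotorula reads of pretreated grain, and the interactions were not refitted without a library. Wickerhamomyces stood at 3.49% against 7.11% on day 0, and its effect differed on day 13 (0.000468% against 0.156%, edgeR adjusted p = 0.00900) and day 26 (0 reads against 0.0994%, 2.1e-04). Glarea went from 1.79% against 2.12% on day 0 to 0.00598% against 0.181% on day 26 (edgeR, -7.27 ± 2.18, adjusted p = 0.0470), and Epicoccum from 0.00681% against 0.172% to 0 reads against 0.983% on day 13 (0.0380).

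Alternaria was lower in pretreated grain on day 0 (0.138% against 8.52%) and its effect differed on day 4 (0.846% against 0.112%, edgeR log2 difference 7.13 ± 1.93 SE, adjusted p = 0.0241) and day 26 (0.644% against 0.145%, 6.15 ± 1.89, 0.0497). Chaetomium, a soil and straw fungus that was picked out after its values were seen, had 0 reads in pretreated and 0.101% in control grain on day 0, and 0.122% and 0 reads on day 4 (edgeR adjusted p = 0.0457). Later days that are not given with a genus did not pass for it. These differences were defined for 119, 122 and 135 of 222 entries on days 4, 13 and 26, the others having a group of 0 reads on each side.

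Mucor was higher in pretreated than in control grain on all 4 days. Scaling is argued against, since the call held on 4 of 4 days under library totals alone and no pretreated library overlapped a control library on these 4 days. A single library is argued against, since the call was lost in 0 of 24 edgeR fits without a library (highest adjusted p = 3.45e-06). Reads leaking alike into every library would give no difference, so the difference itself already settled that comparison. The lowest pretreated library (0.704%) was 12.2-fold above the highest control library (0.0576%). Leaking between particular libraries was not tested. Whether Mucor came with the inoculum, the vessel or the grain may not be told from these tables.

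Escherichia_Shigella was higher after pretreated liquor than after water. Whether a single library carries the call stays open by a rule set after the value was seen, since the call was lost in 1 of 6 edgeR fits (adjusted p = 0.176), where water had 0 reads left and the SE of the log2 fold change went from 2.53 to 3.93, while the fold fell in 0 lost fits and was 10.52 or more on the log2 scale in all 6. Scaling is argued against (edgeR adjusted p = 0.0361 with library totals alone). Water and soil bacteria peaked together with Escherichia_Shigella in water (0.585% in replicate 2) and in pretreated liquor (0.0320% in replicate 2). The peaks did not coincide in control liquor or alcohol. A source made up as water replicate 2 would bring 149.7% and 428% such bacteria to pretreated liquor replicates 1 and 2. No library can hold this, so the comparison could not have passed there and decides nothing for them. Replicate 3 would need 0.665% and had 0 such reads, at most 0.00813 times that share when set to 3 counts. Such a source is argued against for replicate 3 only, and the ratio rests on few Escherichia_Shigella reads in water replicate 2 (0.0109%). A contaminating source of another make-up, or of Escherichia_Shigella alone, stays open.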

How the results depend on the processing

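Library totals, limma and the pooled tests were chosen only after the results were seen, and the cause of a moved value was not tested. Of 45 calls of fungal genera, 43 kept their call with DESeq2, 30 with limma, 37 with no filter, 39 with library totals and 35 with unnamed entries left out. In the simulation of day 13 with no genus changed, DESeq2 made 19.6 false calls and limma 0.3, so a call kept with DESeq2 is a weak check. In fits without a library, 405 calls were kept and 45 lost, of which 6 had a log2 fold change that fell by more than 1 SE of the full fit, 35 did not, and 4 had a contrast that was no longer defined. Bray-Curtis tests of 2 groups could not pass under any setting. Without each library in turn, R2 ran from 0.551 to 0.672 for pretreated against control grain within days, which passed each time, and from 0.250 to 0.376 for the 4 gavage groups, which did not.

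With DESeq2 in place of edgeR, counts of called genera in grain were 16, 17, 37 and 19 on days 0, 4, 13 and 26, 26 and 27 on days 3 and 7 of pretreatment, 20 and 22 from day 0 to day 26 of control and pretreated grain, and 26 for the average. With limma they were 8 on day 0, 3 on day 13, and 9 and 17 on days 3 and 7 of pretreatment. No filter, like unnamed entries left out, gave 1 on day 4 and 0 for control grain over time. In the cecum, no filter gave 2 for control liquor, 1 for alcohol and 1 for the 3 alcohol groups against water, and 2 and 1 for control and pretreated liquor against alcohol. Unnamed entries left out gave 2, 3 and 5 against water, and 2 and 1 against alcohol. DESeq2 gave 4 for control liquor, 3 for pretreated liquor, 4 for alcohol and 4 for the 3 groups against water, limma 0 for pretreated liquor, and Alloprevotella left out 1 for the 3 groups.

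Shannon diversity in grain reversed when entries above 0.01% were counted (-0.333 on day 4, -3.0 on day 13, -1.92 on average) and with Saccharomyces left out (-0.959, -0.554 and -0.399). In the cecum it reversed with unnamed entries left out (0.0549 for pretreated liquor against water, 0.0599 for control liquor against alcohol) and with Alloprevotella left out (-0.0176 for pretreated liquor against alcohol).

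Leaving out unnamed entries moved list shares. Fermenting yeasts became 56.7%, 91.5% and 87.6% in control grain on days 0, 4 and 13, 57.4% in pretreated grain on day 0 and 6.94% on day 7 of pretreatment, with an average difference of -7.65. Starter moulds became 34.7% in pretreated grain on day 0, and 6.45% and 86.7% on days 0 and 7 of pretreatment, field fungi 39.8% on day 0 of pretreatment, and other yeast-like fungi 0.316% in control grain on day 0. Several cecal lists hold unnamed entries themselves, so this setting also deletes list members. The Muribaculaceae group is only Muribaculum and unclassified_Muribaculaceae, and sulfate reducers include unclassified_Desulfovibrionaceae, so their lower shares follow from the deletion. In water, alcohol, control and pretreated liquor, the Muribaculaceae group became 0.177%, 0.0918%, 0.386% and 0.233%. Other Bacteroidales became 50.9%, 54.4%, 43.5% and 44.2% in the same order. In control and pretreated liquor, Lachnospiraceae and Oscillospiraceae became 32.2% and 17.7%, and Erysipelotrichales 3.70% and 2.41%. Control liquor had 3.81% lactobacilli and bifidobacteria, 0.698% enterobacteria and 0.154% grain fermentation genera, water 0.402% sulfate reducers and 6.41% Helicobacter, and alcohol 2.47% Helicobacter. Sulfate reducers in the 3 alcohol groups against water, now without unclassified_Desulfovibrionaceae, reversed to 1.02.

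Without each library in turn, counts of called genera ran from 1 to 2 on day 4, 3 to 7 on day 13, 3 to 5 on day 3 of pretreatment and 0 to 3 for control grain over time. In the cecum they ran from 0 to 4 for control liquor, 0 to 1 for pretreated liquor, 0 to 2 for alcohol and 0 to 3 for the 3 groups against water, and 0 to 2 for either liquor against alcohol. The average difference of fermenting yeasts ran from -11.5 to -5.57 and that of Cladosporium from -0.213 to 0.635. Cecal Shannon differences ran from -0.243 to 0.00771 (control liquor against water), -0.139 to 0.107 (pretreated liquor against water), -0.290 to 0.0429 (alcohol against water), -0.18 to 0.0526 (3 groups against water), -0.152 to 0.151 and -0.0526 to 0.250 (control and pretreated liquor against alcohol) and -0.0359 to 0.207 (both liquors). Escherichia_Shigella, and enterobacteria, over the 4 groups ran from 3.26 to 12.5. For the 3 groups against water, other Bacteroidales ran from -6.06 to 2.06, Lachnospiraceae and Oscillospiraceae from -4.38 to 2.92, Erysipelotrichales from -0.0309 to 1.75, the mucin degrader from -0.0600 to 0.00959, Alloprevotella from -5.29 to 2.65, Lachnospiraceae_NK4A136_group from -2.97 to 0.269, Erysipelatoclostridium from -0.0487 to 1.70 and Odoribacter from -1.20 to 0.340.

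Libraries of the same number did not pair across groups (mean correlation 0.00562 in fungi and 0.0359 in the cecum). With the number as a block, counts were 5, 2, 5 and 3 on days 0, 4, 13 and 26, 5 and 7 on days 3 and 7 of pretreatment, 3 and 7 for control and pretreated grain over time and 9 for the average, and the cecal counts did not move. Alternatives for grain bacteria, pseudocounts, centred log ratios, thresholds without a test and a denominator without organelles were not run, the tables being counts with a test and naming 0 organelles.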

Other observations

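The test of mixing and the regrouped counts were chosen only after the results were seen.

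Grain at the start of pretreatment had a Shannon diversity of 3.50 ± 0.0309 (SD, n = 3), with 37.4% to 41.6% of its reads in entries without a genus name. Filobasidium, a yeast of leaf surfaces, held 6.23% ± 2.71, the cereal pathogen Fusarium 3.27% ± 1.26, the field fungus Cladosporium 3.16% ± 1.46 and the storage mould Penicillium 1.58% ± 0.485. Shannon diversity was 2.59 ± 0.941 on day 3 and 1.65 ± 0.261 on day 7 of pretreatment, and these were not tested.

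Pretreated grain on day 0 of formal fermentation could be a mixture of control grain on day 0 and grain on day 7 of pretreatment. A mixing weight of 0.347 for the pretreatment grain, fitted to Mucor and Rhizopus shares, gave 9.95% Mucor and 9.94% Rhizopus, against 9.42% and 10.5% measured. It predicted 30.6% Saccharomyces against 45.2% measured, 14.6 points more, with a combined SD of 6.81 over 27 library triples and differences from 6.42 to 29.2. The measured share was higher in every triple, but the triples reuse the same few libraries. A rule of over 2 combined SDs, set after the values were seen, was only narrowly met. Mucor and Rhizopus, which set the weight, also spread widely between the libraries of day 7. Predictions for Candida (0.136% against 1.49%), Aspergillus (16.4% against 9.27%), Alternaria (5.68% against 0.138%) and Wickerhamomyces (4.65% against 3.49%) also differed. At any weight, a mixture lies between its 2 sources, control grain on day 0 and grain on day 7 of pretreatment. Measured Candida (1.49% ± 0.698) lay above both source means (0.0353% and 0.326%), and so did Saccharomyces, though near its control share (43.9%). Aspergillus (sources 14.9% and 19.3%) and Alternaria (8.52% and 0.344%) lay below both, and Wickerhamomyces (7.11% and 0.0162%) between them. Simple mixing of these 2 communities alone is thus argued against for Candida, and narrowly for Saccharomyces. Mixing with other sources and growth stay open.

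Libraries were regrouped and genera called again with edgeR. With 3 libraries against 3 there are 10 splits, all of them run, too few to tell, since the real split always counts and the share never falls under 0.1. In grain, the real split gave 5 calls on day 0 (highest other 0), 2 on day 4 (0), 5 on day 13 (2), 3 on day 26 (2), 6 on day 7 of pretreatment (0), 4 for control grain over time (2) and 5 for pretreated grain over time (0), each reached by 1 of 10 splits. On day 3 of pretreatment 3 of 10 splits gave as many as the real 5, with 6 as the highest other. Both other splits put day 3 replicate 1, which held 11% starter moulds against 57.9% and 61.0% in replicates 2 and 3, with 2 libraries of day 0 (5 and 6 calls). In the cecum, pretreated liquor against water gave 1 (highest other 0, 1 of 10 splits), while the other 5 pairs gave 0, reached by 10 of 10 splits, with 1 as the highest other for alcohol against water and 0 elsewhere.

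For the average over the 4 days, 1 of 100 groupings within days, the real one and others drawn at random, gave as many as the real 10 calls, with 8 as the highest other, which is in line with a difference between the fermentations. For the 3 alcohol groups against water, 100 of 100 groupings gave as many as the real 0, and the highest other was 4. The average was defined for 81 of 222 entries in the real grouping, and how many were defined in the others was not counted.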
